A study of Mus musculus with 16 samples.

How the data were processed

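RNA was measured in 16 mouse mammary tumours, 4 in each of 4 groups. Per the labels, tumours of MMTV-PyMT transgenic mice aged 12 weeks, a strain in which the polyoma middle T antigen drives mammary cancer, were transplanted into the mammary fat pad of FVB recipients. The recipients were given vehicle, an antibody against PD-L1 at 5 mg/kg 2 times a week, sonidegib at 20 mg/kg each day, or both, over 28 days. Sonidegib inhibits Smoothened, the signal transducer of the Hedgehog pathway. RNA was isolated with Qiazol, and the libraries were stranded and depleted of ribosomal RNA per the labels' protocols, while another label names polyadenylated RNA as the molecule. This conflict was not resolved. The labels number the tumours within each group and name no litter, donor, batch or day. Nothing states whether tumours of different numbers came from separate donors, so the p-values measure the spread between these tumours.

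The deposited values are FPKM (fragments per kilobase of transcript and M mapped fragments, M being mega), 1 column per library and 55146 genes, each with a versioned Ensembl identifier and a symbol. The submitters' processing notes name TopHat, Cufflinks and the builds GRCm38.p6 and mm10, and the versions and the annotation are not given in the sources used here. Each column was matched to its library by the S number that the library's description carries, written in the column with a leading zero. These S numbers run through the groups in turn: vehicle, anti-PD-L1, sonidegib and combination. An effect of library order therefore cannot be told apart from treatment. All 16 columns were used. Of the identifiers, 53913 matched GENCODE release M21 (GRCm38) with their version and 54468 without it. Coordinates, strand, biotype, GC content and transcript length were taken from that release. FPKM divides out length and the number of mapped fragments, so a few very abundant transcripts can shift all others, and Cufflinks divides fragments between overlapping genes by a model.

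Whole fragment counts could not be recovered from the values. The depth was estimated from the FPKM step that 1 fragment is worth in 4967 genes with a single transcript longer than 2 kb, after subtracting 200 bp for the fragment. The steps were smeared, so the estimates of 34.6 to 56.6 M fragments per library are approximate. At these depths 1 fragment on a 2 kb transcript is worth 0.0098 to 0.0161 FPKM. A value of 0 can be a failed estimate: 385 tested genes were listed at 0 in at least 1 library, and 30 of these had a median of at least 10 FPKM. For such genes only the listed values are given.

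Genes with at least 1 FPKM in at least 4 libraries were tested, 15105 in all. The values were transformed to log2(FPKM + 1) without further scaling, and all log2 changes are on this scale, which understates the change of genes near 1 FPKM. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 16 libraries, with an intensity trend and robust variance estimation. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison at a threshold of 0.05. The comparisons were the difference across the 4 groups, the 6 pairwise differences, and the interaction of the 2 drugs. Of 29 gene lists for pathways, cell types and RNA quality with 534 entries, 530 had a value and 4 (Foxc2, Mvd, Acta1 and Ahsp) were not analysed here. The cornified skin list had 1 tested member, so 28 lists were tested, with camera in limma at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares the members of a list with all other genes, and the median of a list can differ in sign from its test. The score of a list in a library is the mean log2 deviation of its members from their means over the 16 libraries, minus the median deviation of all tested genes, and scores were compared by exact two-sided permutation tests. The p-values of the scores are not adjusted over the 28 lists and 6 comparisons, so some would reach the smallest possible value by chance. Genes under the filter were compared by exact two-sided permutation tests of the mean FPKM, whose smallest possible p is 0.0286 with 4 against 4 libraries.

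The groups, tests, gene lists, rule for named genes and a set of other settings were fixed before the data were examined. The plan provided for read counts or FPKM, and the FPKM test was used. The rule names, per comparison, the 10 largest rises and 10 largest falls by log2 change among genes past the threshold with a mean of at least 1 FPKM and a symbol that is no predicted or clone name. It adds members of the lists past the threshold, with 2 to 4 examples a list in the text. Where fewer than 5 genes pass, it adds the 5 genes with the lowest p. Cd274, Pdcd1, Gli1, Ptch1, Hhip, Cers4, Cers6, Cd8a, Cd4, Foxp3, Gzmb and Ifng are named whatever their test. Some genes that the rule names are not reported here.

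The other settings fixed then were quantile normalization, no filter, a mean of at least 1 FPKM, a pseudocount of 0.1, the replicate number as a block, fits on only the 2 groups compared, camera with an estimated correlation, fry, and leaving out each library in turn. Added after seeing the data were median-of-ratios scaling, removal of each library's loess trends (span 0.3) with GC content alone and with GC content and transcript length, the GC slope of each library as a covariate, array weights, genes above 0 in all 16 libraries, and omission of the 5 libraries with a GC slope above 2. The GC slope is the slope of a library's log2 deviation from the gene means on the GC fraction of the transcripts. GC content and length were known for 98.6% of the tested genes. The fit was tested on simulated data for the combination against vehicle, with 200 of 15105 genes changed. It called 36.7%, 92% and 98.3% of genes simulated with log2 changes of 1, 2 and 3, and 5.57% of the calls were false. The simulated noise was independent between genes and held no GC trend, so this false share does not carry over to the real libraries. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.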

Results

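Gene expression was measured in 16 transplanted PyMT mammary tumours treated with vehicle, anti-PD-L1, sonidegib or both drugs, with 4 libraries per group. The estimated depth was 34.6 to 56.6 M fragments per library. Vehicle replicate 3 had the lowest estimate, and its 11361 genes with at least 1 FPKM compare with 13107 to 14784 in the other 15 libraries. Vehicle replicate 2, with nearly the same estimate (34.7 M), had 13482 such genes. The median log2 deviation of vehicle replicate 3 from the gene medians was -0.764, against -0.129 to 0.149 in the other 15 libraries. Without scaling, this low library enters each comparison with vehicle. Spearman's rho between libraries of a group was 0.869 to 0.962 over genes.

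Across the 4 groups, the chemokine gene Ccl8 and Ly6c1, which encodes a surface protein of the Ly6 family, were highest in the tumours given both drugs. Ccl8 was at 6.33 ± 3.09 FPKM (SD, n = 4) with vehicle, 19.8 ± 8.39 with anti-PD-L1, 24.2 ± 12.1 with sonidegib and 73 ± 16.8 with the combination. Ly6c1 was at 2.54 ± 0.77, 4.73 ± 2.45, 5.98 ± 2.18 and 17.2 ± 5.49 FPKM in the same order. The noncoding RNA gene AY036118 was the remaining call, listed below 0.001 FPKM in 7 of the 8 libraries without sonidegib and at 264 to 3630 FPKM in all 8 libraries with it. Ccl8 (ENSMUSG00000009185.2) lies on chromosome 11 at 82115185 to 82116799 of GRCm38, on the plus strand, and Ly6c1 (ENSMUSG00000079018.10) on chromosome 15 at 75044018 to 75048830. AY036118 (ENSMUSG00000105361.1, lincRNA) lies on chromosome 17 at 39847113 to 39848035 on the minus strand, inside the ribosomal RNA gene CT010467.1 on that strand and overlapping Gm42418 on the other, so its reads are not uniquely its own. The series names this comparison across all groups as its primary one. Limma with Benjamini-Hochberg adjustment called these 3 of 15105 genes (adjusted p = 0.0257 for each), and 3579 had an unadjusted p under 0.05. The number of calls was 3331 without vehicle replicate 4, 1843 without combination replicate 1, 14 without sonidegib replicate 2, and 0 or 1 without each of 8 other libraries. It was 0 with quantile normalization, with median-of-ratios scaling, with a pseudocount of 0.1, with the GC trend or both trends removed, and with the GC slope as a covariate.

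**Figure D1:**
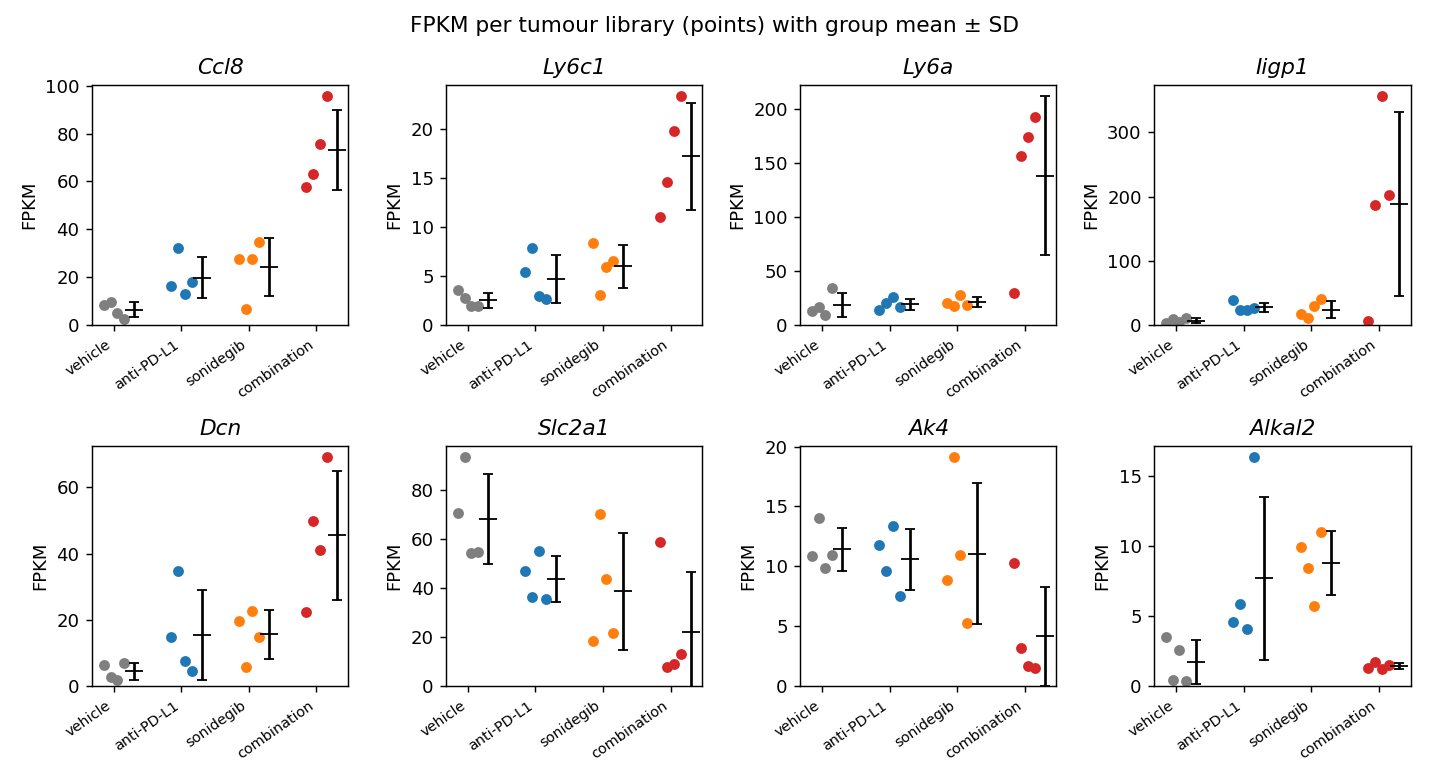
FPKM (vertical axes, linear) of 8 genes in each of the 16 libraries (points), with the mean ± SD of each group of 4 beside them; error bars that would pass below 0 end at the axis. Ccl8 and Ly6c1 are higher in each of the 4 combination libraries than in any other library, while Iigp1 is at 6.94 FPKM in combination replicate 1 and at 188 or more in the other 3.

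Anti-PD-L1 alone was compared with vehicle to ask what checkpoint blockade changed in the tumours. The 5 genes with the lowest p included Gk, the glycerol kinase, at 7.34 ± 4.19 FPKM with vehicle and 17.3 ± 2.34 with anti-PD-L1 (log2 difference 1.26, SE 0.29), and Alkal2, a ligand of the ALK receptor, at 1.71 ± 1.59 and 7.69 ± 5.82 FPKM (1.69, SE 0.40). All 4 anti-PD-L1 libraries exceeded all vehicle libraries for both genes. Cdca7l (1.18), Cdkal1 (1.25) and Gm49322 (-1.07) completed these 5, and none passed the threshold (adjusted p = 0.158 for each by limma). The proliferation and cell cycle list was higher relative to other genes, with a median log2 change of 0.64 over 24 members (camera, adjusted p = 0.032; adjusted p = 0.993 with an estimated correlation). Of its members 0 passed over all genes and 9 adjusted over the list alone, among them Mki67 (1.35, SE 0.40), Top2a (1.28, SE 0.42) and Ccnb1 (1.23, SE 0.37). Its score differed from vehicle by 0.387 with anti-PD-L1 (SE 0.246, exact permutation p = 0.2) and by 0.323 with sonidegib (SE 0.219, 0.314). Between sonidegib and anti-PD-L1 the score differed by -0.0639 (exact permutation p = 0.657), so this test does not set anti-PD-L1 apart from sonidegib. The immediate early and heat shock list was lower relative to other genes, with a median of -0.23 over 14 members, 0 passing by either count (adjusted p = 0.00174; adjusted p = 0.993 with an estimated correlation). The median gene was 0.30 higher with anti-PD-L1 on the log2 scale. Vehicle replicate 3 contributed to this, with a median log2 deviation of -0.764 against -0.129 to 0.0385 in the other vehicle libraries. Limma called 0 genes, with 3712 at an unadjusted p under 0.05. Without vehicle replicate 4 the number was 3929, and the proliferation call was lost without vehicle replicate 2, vehicle replicate 3 or anti-PD-L1 replicate 4 (highest adjusted p = 0.356). With the GC trend removed the immediate early list was not called (adjusted p = 0.313; 0.297 with both trends removed), with a median relative to all genes of -0.53 before and -0.22 after, while the proliferation list was (0.00211 and 0.00269).

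Sonidegib alone was compared with vehicle to ask what Hedgehog inhibition changed. Ptch1, the Hedgehog receptor and a target of the pathway, was at 3.52 ± 1.28 FPKM with vehicle and 3.2 ± 0.835 with sonidegib (log2 difference -0.07, SE 0.23, adjusted p = 0.844 by limma). The Hedgehog list was lower relative to other genes, which had a median log2 change of 0.33, although its own median was -0.04 and 0 of its 9 tested members passed (camera, adjusted p = 0.021; adjusted p = 0.876 with an estimated correlation). Its median relative to all genes was -0.37 with sonidegib and -0.43 with anti-PD-L1, and -0.40 and -0.145 with the GC trend removed. Its score differed by -0.452 between sonidegib and vehicle (exact permutation p = 0.0857). Between sonidegib and anti-PD-L1 the score differed by -0.137 (exact permutation p = 0.4), so this test does not set sonidegib apart from anti-PD-L1. The type I interferon and luminal lists were also called lower (adjusted p = 0.021 for each), with medians of -0.00235 over 24 and 0.08 over 19 members, so the luminal median and its test differ in sign. Hypoxia and glycolysis (median -0.14 over 21 members, adjusted p = 0.00114) and immediate early and heat shock genes (median -0.29 over 14, adjusted p = 0.000164) completed the 5 lists called lower. In these 4 lists 0 members passed by either count, and each had an adjusted p = 0.876 with an estimated correlation. The 5 genes with the lowest p were AY036118, Alkal2 (log2 difference 2.02, SE 0.40), the autophagy gene Dram1 (1.24, SE 0.26), the DNA repair gene Tdp1 (0.95, SE 0.20) and Gadd45a (1.14, SE 0.24), a growth arrest gene, all with adjusted p = 0.127. All 4 sonidegib libraries exceeded all vehicle libraries for each of them. Limma called 0 genes, with 4131 at an unadjusted p under 0.05. The number was 3980 without vehicle replicate 4. The Hedgehog call was lost without vehicle replicate 2 or sonidegib replicate 4 (highest adjusted p = 0.0949), type I interferon without vehicle replicate 3 or sonidegib replicate 4 (0.428) and luminal without vehicle replicate 4 or sonidegib replicate 1 (0.107). With the GC trend removed none of the 5 lists was called (adjusted p = 0.112 to 0.229). Their medians relative to all genes went from -0.37 to -0.40 for Hedgehog, -0.33 to -0.26 for type I interferon, -0.25 to -0.26 for luminal, -0.47 to -0.30 for hypoxia and -0.62 to -0.40 for immediate early genes.

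The combination was compared with vehicle to ask what both drugs together changed. Iigp1, an interferon-inducible GTPase, rose from 6.87 ± 3.52 to 188 ± 143 FPKM (SD, n = 4; log2 change 3.82, SE 0.92, adjusted p = 0.0357 by limma). Ccl8 rose by 3.42 (SE 0.42, adjusted p = 0.00262), and the proteoglycan genes Dcn and Lum by 3.15 (SE 0.55) and 2.75 (SE 0.51). Postn (2.83), Ly6a (2.70), Wfdc17 (2.69), Rgs2 (2.54), mt-Atp8 (2.48) and Cbr2 (2.48) completed the 10 largest rises. Slc2a1, the glucose transporter GLUT1, fell from 68.1 ± 18.4 to 22.1 ± 24.4 FPKM (log2 change -2.04, SE 0.50, adjusted p = 0.0346). The other large falls were in Hspa1a (-1.69), Ak4 (-1.55), Nes (-1.53), Zfp395 (-1.50), Celsr2 (-1.46), Espn (-1.42), Atn1 (-1.41), Slco2a1 (-1.41) and Fgfr1 (-1.35). All 4 combination libraries lay beyond all vehicle libraries for Ccl8, Dcn, Lum, Wfdc17, Cbr2, Hspa1a and Atn1, and 3 of 4 for the others of these 20. Iigp1 (ENSMUSG00000054072.12) lies on chromosome 18 at 60376027 to 60392634 and Slc2a1 (ENSMUSG00000028645.11) on chromosome 4 at 119108711 to 119137983 of GRCm38, both on the plus strand.

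Limma called 1703 of 15105 genes between combination and vehicle, 1559 higher and 144 lower, so 91.5% of the calls were higher, and 5081 genes had an unadjusted p under 0.05. The median gene was 0.26 higher in the combination without scaling and 0.00962 higher after median-of-ratios scaling. That scaling called 2772 genes, 1539 higher and 1233 lower (55.5% higher), and quantile normalization 2634, 1326 higher and 1308 lower (50.3% higher). Genes called higher had a median GC content of 44% and those called lower 57.9%, against 50% in genes not called. The GC slope averaged 2.76 ± 2.24 (SD, n = 4) in the vehicle libraries and -1.95 ± 2.75 in the combination libraries (difference -4.71, exact permutation p = 0.0571, Benjamini-Hochberg adjusted 0.228 over 6 comparisons). Vehicle replicate 4, at -0.513, and combination replicate 1, at 2.13, lay apart from the other libraries of their groups. The first principal component held 39.3% of the variance and followed the GC slope over the 16 libraries (Pearson's r = -0.901, Spearman's rho = -0.971, both permutation p = 1e-05, the smallest that 100000 permutations can give). Without the 2 most extreme libraries r was -0.959. The count was 572 with the GC trend removed, 28 with the GC and length trends removed and 0 with the GC slope as a covariate. It was 10, 6, 3 and 4953 without vehicle replicates 1, 2, 3 and 4, and 4245, 8, 514 and 3 without combination replicates 1, 2, 3 and 4.

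**Figure D2:**
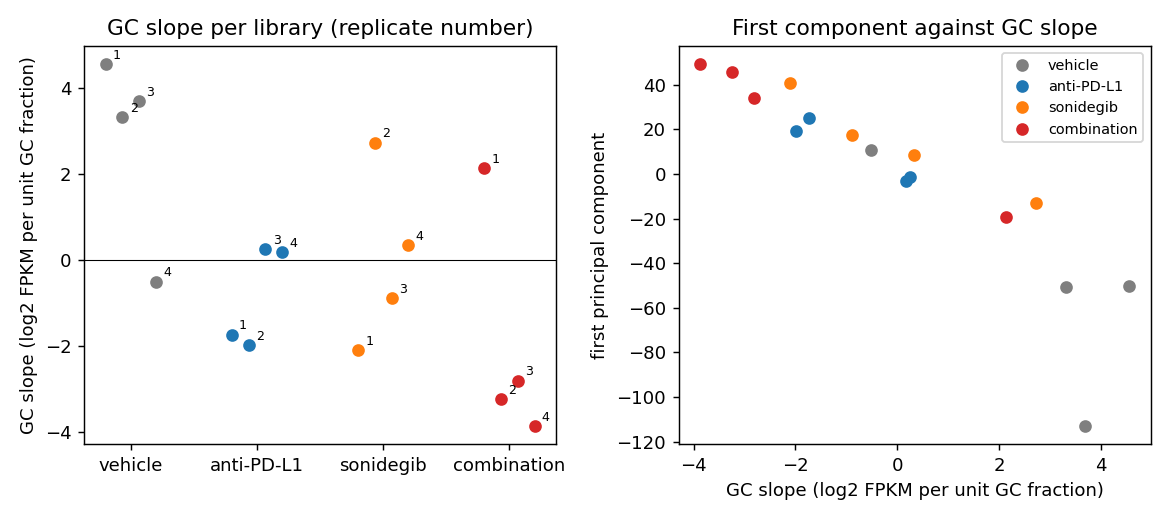
Left, GC slope of each library (log2 FPKM per unit GC fraction) by group, with the replicate number beside each point. Right, first principal component of log2(FPKM + 1) against the GC slope, coloured by group; 3 of the 4 vehicle libraries have slopes of 3.32 to 4.55 and 3 of the 4 combination libraries slopes of -3.87 to -2.81.

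Of the immune lists, camera called those of T cells and of antigen presentation higher in the combination than in vehicle. Of 23 listed T cell markers 7 passed the filter and were tested, and 6 of these rose, over all genes and adjusted over the list alone, with a list median of 1.22. The filter keeps a gene that reaches 1 FPKM in 1 group alone, so the tested members of a list near that level favour a difference between groups. Cd3g of the T cell receptor complex rose from 0.234 ± 0.233 to 3.62 ± 2.34 FPKM (log2 change 1.74, SE 0.33, adjusted p = 0.0278 by limma), and Trbc2, the receptor beta constant chain, by 1.98 (SE 0.51). Camera gave the T cell list an adjusted p = 0.00103, and an adjusted p = 0.625 with an estimated correlation. The mean score of the list was -0.299 in combination replicate 1 and 0.814 to 1.13 in the other 3, against -0.525 to 0.0613 with vehicle (difference 0.973, SE 0.354, exact permutation p = 0.0857). Among 28 antigen presentation and interferon-gamma genes 9 rose, and 17 did adjusted over the list alone (median 1.15, adjusted p = 0.000137; adjusted p = 0.914 with an estimated correlation). The mean scores of this list differed by 0.934 (SE 0.449, exact permutation p = 0.114). Its members that rose included Gbp2 (1.83), an interferon-inducible GTPase, and B2m (1.77), the light chain of MHC class I. Of 19 listed cytotoxic effectors only 3 passed the filter, which rose by either count, Ccl5 by 1.13, Nkg7 by 1.26 and Gzmb by 0.71 (SE 0.22, adjusted p = 0.0469), although camera did not call the list (adjusted p = 0.0617). The mean scores of these 3 members differed by 0.788 (SE 0.239, unadjusted exact permutation p = 0.0286, the smallest possible), a difference that the filter favours. Of 18 macrophage and monocyte markers 3 rose, and 4 adjusted over the list alone, among them Ccr2 (2.00, SE 0.34) and Mrc1 (1.29, SE 0.25), with camera at an adjusted p = 0.1. Camera did not call the B and plasma cell (adjusted p = 0.731), dendritic cell (0.956), neutrophil (0.668) and type I interferon (0.589) lists. With both trends removed, the T cell and antigen presentation lists stayed called (adjusted p = 0.00158 and 3.08e-06), while the log2 change of Gzmb was 0.11 (adjusted p = 0.804).

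Genes of hypoxia and glycolysis were lower with the combination than with vehicle, with a median log2 change of -0.84 over 21 members. Slc2a1 and Car9, the carbonic anhydrase IX gene (-0.98, SE 0.30, adjusted p = 0.0456 by limma), fell over all genes, and Egln3 (-0.84, SE 0.28) too adjusted over the list alone, which makes 3. Camera gave an adjusted p = 1.26e-10, and an adjusted p = 0.625 with an estimated correlation. The mean score of the list was 0.503 in combination replicate 1, inside the 0.322 to 0.609 of vehicle, and -1.12 to -0.896 in the other 3 (difference -1.09, SE 0.388, exact permutation p = 0.0857). Immediate early and heat shock genes were lower as well, with a median of -0.69 over 14 members (adjusted p = 2.1e-05; adjusted p = 0.625 with an estimated correlation). The score of this list was 0.317 to 0.734 in the vehicle libraries and 0.231 at most in the 12 others. Its differences from vehicle were -0.514, -0.608 and -0.892 for anti-PD-L1, sonidegib and the combination. Each had an unadjusted exact permutation p = 0.0286, the smallest possible, and the 3 comparisons share the vehicle libraries. In the combination the median of this list relative to all genes went from -0.95 to -0.54 with the GC trend removed and to -0.62 with both trends removed (adjusted p = 0.0235 and 0.0123). Of its 14 members 1 fell over all genes, Hspa1a, and 2 adjusted over the list alone. Of 13 mitochondrially encoded genes 8 rose, and all 13 did adjusted over the list alone (median 1.60, adjusted p = 0.000137; adjusted p = 0.914 with an estimated correlation), among them mt-Co2 (2.23, SE 0.60). The median of this list relative to all genes went from 1.34 to 0.86 with the GC trend removed and to 0.66 with both trends removed, where the list stayed called (adjusted p = 0.00181) and each of the 8 genes lost its call (mt-Co2 1.31, adjusted p = 0.069). These transcripts summed to 41949 and 38524 FPKM in combination replicates 2 and 4, against 3552 to 18642 in the other 14 libraries.

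The fibroblast and matrix list had 6 of 24 members higher, and 8 adjusted over the list alone, without a call by camera (adjusted p = 0.0716). They included Mmp2 (1.05, SE 0.25), a matrix metalloprotease, and Pdgfra (1.09, SE 0.29). The sphingolipid and ceramide list, chosen for the series' title, had 3 of 29 tested members higher by either count and a median of 0.27 (camera, adjusted p = 0.589). These were Sptssa (1.57, SE 0.36), a subunit of serine palmitoyltransferase, and Ormdl1 (1.12, SE 0.32) and Ormdl2 (1.08, SE 0.32), which restrain that enzyme. With both trends removed their log2 changes were 0.71, 0.42 and 0.39 (adjusted p = 0.0562, 0.121 and 0.241). Among 8 tested checkpoint genes 1 rose by either count, the costimulatory ligand Cd86 (1.14, SE 0.32; 0.49 with both trends removed, adjusted p = 0.23), and the list was not called (adjusted p = 0.956). The Hedgehog list had a median of -0.16 and 0 of 9 members past the threshold by either count (adjusted p = 0.0617).

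**Figure D3:**
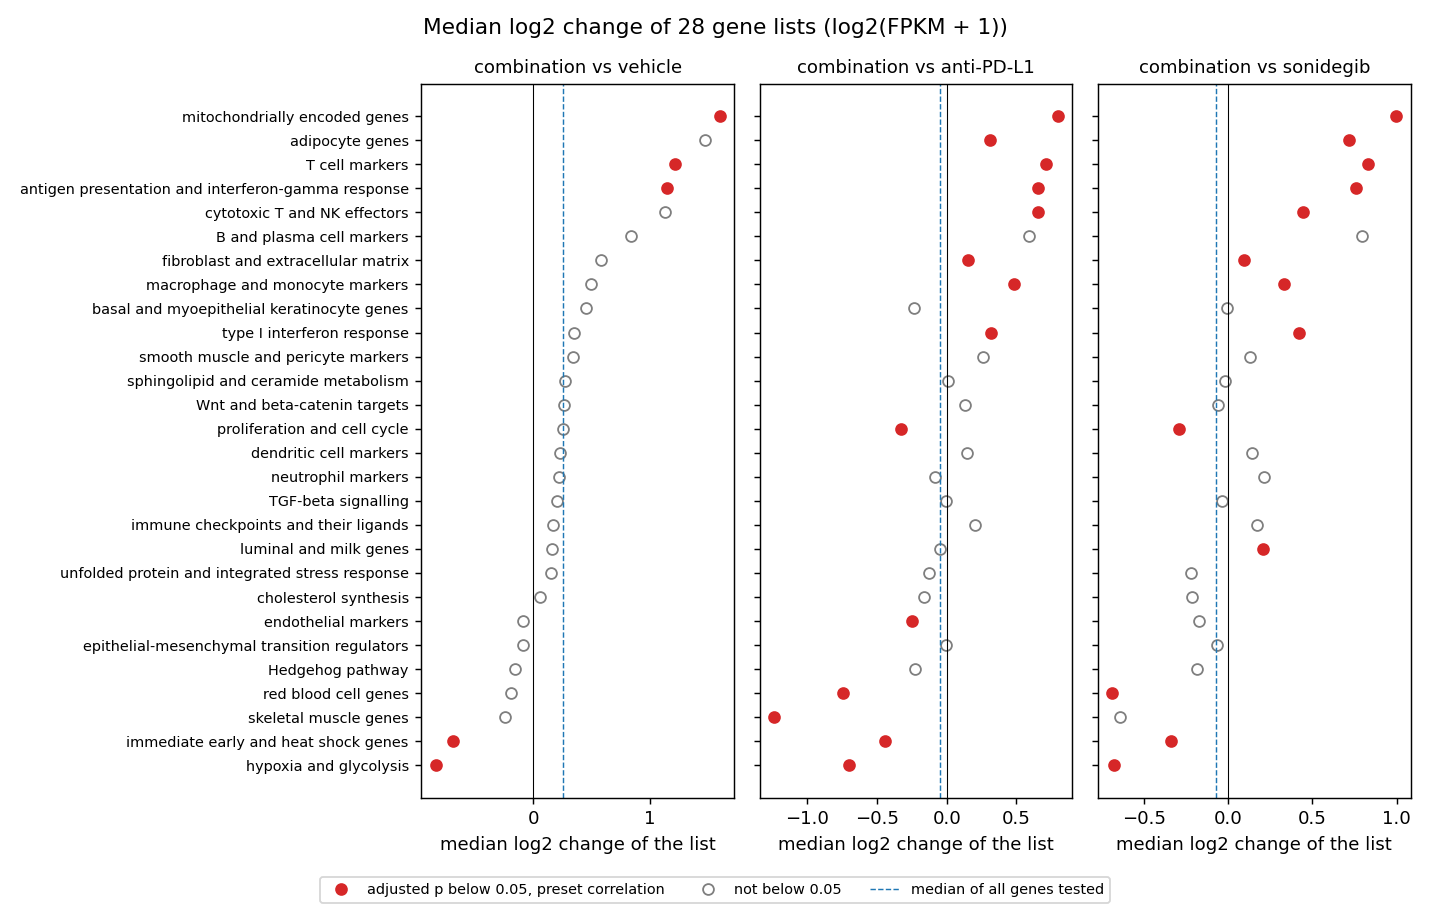
Median log2 change of the 28 tested gene lists for the combination against vehicle, anti-PD-L1 and sonidegib (horizontal axes, log2(FPKM + 1) scale), with the median of all tested genes as a dashed line. Filled points are lists called by camera at the preset correlation, 5, 14 and 13 in the 3 comparisons; none was called with an estimated correlation.

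The combination was compared with anti-PD-L1 alone to ask what adding sonidegib changed. AY036118 was higher in all 4 combination libraries, with a log2 change of 11.35 (SE 1.44, adjusted p = 0.0488 by limma), at 2680 ± 722 FPKM. The next lowest p belonged to Ly6c1 (log2 difference 1.71, SE 0.31), Ly6a (2.53, SE 0.47), the prolyl hydroxylase gene Egln3 (-1.29, SE 0.28) and Alox5ap (1.27, SE 0.28), which activates 5-lipoxygenase, with adjusted p of 0.208 to 0.548. In each, all 4 combination libraries lay beyond all anti-PD-L1 libraries. The antigen presentation (median 0.66, adjusted p = 5.18e-13), T cell (0.71, 1.81e-06), macrophage (0.48, 1.2e-06), cytotoxic (0.66, 0.000444) and type I interferon (0.32, 0.000109) lists were higher relative to other genes. Only 7 of 23 T cell and 3 of 19 cytotoxic members were tested, after a filter that favours a difference between groups. With an estimated correlation the adjusted p of the 14 lists called here were 0.223 to 0.646. The unadjusted exact permutation p of the list scores was 0.143 for antigen presentation and T cells, 0.0286 (the smallest possible) for macrophages, 0.0571 for cytotoxic effectors, 0.371 for type I interferon and 0.114 for hypoxia. Mitochondrially encoded (0.80), matrix (0.15) and adipocyte (0.31) lists were also higher. Lower were hypoxia and glycolysis (median -0.70, adjusted p = 4.9e-12), proliferation (-0.33), endothelial (-0.25), skeletal muscle (-1.24), red blood cell (-0.74) and immediate early genes (-0.44). Over all genes 0 members of these 14 lists passed, and adjusted over the list alone Ccl5 and Gzmb of the cytotoxic list, 3 macrophage markers with Ccr2 (1.25, SE 0.34), and Egln3 did. Limma called the single gene above, with 873 at an unadjusted p under 0.05, and 216 genes without combination replicate 1. The AY036118 call was lost in 22 of 30 alternatives. With 1 of the 16 libraries left out, the calls of 7 lists were lost: type I interferon without 1 library (combination replicate 4, adjusted p = 0.196), immediate early without 1 (combination replicate 2, 0.296), proliferation without 2 (highest 0.0614), red blood cell without 2 (0.168), adipocyte without 3 (0.634), skeletal muscle without 3 (0.899) and endothelial without 4 (0.251).

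The combination was compared with sonidegib alone to ask what adding anti-PD-L1 changed. Ly6a, the stem cell antigen gene, was at 139 ± 73.8 FPKM with the combination and 21 ± 4.6 with sonidegib (log2 difference 2.39, SE 0.47, adjusted p = 0.641 by limma), higher in all 4 combination libraries. Alkal2 (-1.98, SE 0.40), the alternatively activated macrophage gene Retnla (2.33, SE 0.48), Ly6c1 (1.40, SE 0.31) and Plac8 (1.57, SE 0.37) completed the 5 lowest p, with adjusted p of 0.641 to 0.959. The antigen presentation (median 0.76, adjusted p = 4.32e-19), T cell (0.83, 1.91e-09), macrophage (0.33, 3.35e-06), type I interferon (0.42, 8.97e-07) and cytotoxic (0.45, 0.00316) lists were higher relative to other genes. The filter limits the T cell and cytotoxic lists here as well. With an estimated correlation the adjusted p of the 13 lists called here were 0.18 to 0.649. The scores had exact permutation p of 0.143 for antigen presentation and cytotoxic effectors, 0.0857 for T cells, 0.0571 for macrophages, 0.314 for type I interferon and 0.2 for hypoxia. Mitochondrially encoded (1.00), adipocyte (0.72), luminal (0.21) and matrix (0.09) lists were higher too. Hypoxia and glycolysis (-0.68, 1.05e-09), proliferation (-0.29), red blood cell (-0.69) and immediate early genes (-0.34) were lower. Adjusted over the list alone, 6 of 7 T cell markers were higher, among them Cd3g (1.30, SE 0.33), and 2 macrophage markers, Ccr2 (1.21, SE 0.34) and Ly6c2 (1.19, SE 0.33), while over all genes 0 members passed. Limma called 0 genes, with 647 at an unadjusted p under 0.05, and 117 without combination replicate 1. With 1 of the 16 libraries left out, the calls of 6 lists were lost: adipocyte without 1 library (combination replicate 1, adjusted p = 0.0873), matrix without 1 (sonidegib replicate 4, 0.0629), luminal without 2 (highest 0.548), proliferation without 2 (0.134), red blood cell without 4 (0.392) and immediate early without 6 (0.939).

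Between the single treatments, AY036118 was higher in all 4 sonidegib libraries (log2 difference 9.96, SE 1.44, adjusted p = 0.189 by limma). Itprid1 (-1.47), Ppp1r1b (1.62), Klk1b26 (-1.12) and Alox5ap (1.21) had the next lowest p, with adjusted p = 1 for each. The luminal and milk list was lower with sonidegib than with anti-PD-L1, with a median of -0.26 over 19 members and 0 past the threshold by either count (camera, adjusted p = 0.0113; adjusted p = 0.996 with an estimated correlation). Its call was lost without 4 of the 16 libraries, anti-PD-L1 replicates 3 and 4 and sonidegib replicates 1 and 3 (highest adjusted p = 0.159). Limma called 0 genes, with 316 at an unadjusted p under 0.05.

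The interaction asked whether the effect of the combination differed from the sum of both single effects. Alkal2 was the gene called, with a mean of 1.71 ± 1.59 FPKM with vehicle, 7.69 ± 5.82 with anti-PD-L1, 8.77 ± 2.3 with sonidegib and 1.42 ± 0.224 with the combination (log2 interaction -3.68, SE 0.56, adjusted p = 0.049 by limma). All 4 libraries of each single treatment were above all 4 of the combination. Ska3, Prelid2 and Tdp1 were among the genes with the next lowest p, with log2 values of -1.26, -1.72 and -1.09 and an adjusted p = 0.485 each. The median gene had an interaction of -0.35, to which the low median log2 deviation of vehicle replicate 3 (-0.764) contributed, and 1492 genes had an unadjusted p under 0.05. The Alkal2 call was lost in 24 of 29 alternatives, both scalings and the removal of either trend among them.

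The genes of the series' title and of the drugs' targets were mostly low. Cd274, which encodes PD-L1, was at 0.424 ± 0.121 FPKM with vehicle, 0.646 ± 0.061 with anti-PD-L1, 0.63 ± 0.319 with sonidegib and 1.1 ± 0.722 with the combination (combination against vehicle, exact permutation p = 0.0857). Cd8a, the cytotoxic T cell coreceptor, was at 0.315 ± 0.185 with vehicle and 1.4 ± 0.816 with the combination (exact permutation p = 0.0571). Pdcd1 was at 0.302 ± 0.078 and 0.873 ± 0.411, Cd4 at 0.535 ± 0.189 and 0.691 ± 0.251, and the regulatory T cell factor Foxp3 at 0.0991 ± 0.0693 and 0.137 ± 0.0919. The ceramide synthase gene Cers4 was at 0.302 ± 0.044 with vehicle, 0.369 ± 0.0902 with anti-PD-L1, 1.51 ± 1.84 with sonidegib (highest library 4.22) and 0.624 ± 0.203 with the combination (combination against vehicle, exact permutation p = 0.0286, against sonidegib 0.514), and Cers6 at 2.57 ± 1.06 and 2.77 ± 0.367 (limma, adjusted p = 0.782). Ifng was listed at 0 in all 4 vehicle libraries and reached 0.525 FPKM at most (combination and sonidegib each against vehicle, exact permutation p = 0.0286). Of the Hedgehog targets, Gli1 had group means of 0.0907 to 0.139 FPKM, Hhip was at 0.0133 FPKM or less in every library, and Ptch1 was at 2.58 ± 0.528 with the combination (log2 difference from vehicle -0.30, adjusted p = 0.376 by limma). The 54 exact tests of the 9 genes under the filter had Benjamini-Hochberg adjusted p of 0.483 or more, but with a smallest possible p of 0.0286 any could pass only if most of them had a p that small, so this does not show that these genes were unchanged.

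The 3 comparisons against vehicle share its 4 libraries. Over genes, which are not independent replicates, the log2 changes with sonidegib and with the combination had r = 0.818, against 0.5 in simulations without effects. With the vehicle libraries split, so that none is shared, the mean r was 0.521, against -0.000808 in such simulations. The values were 0.789, 0.497, 0.424 and 0.00104 for anti-PD-L1 with sonidegib, and 0.749, 0.497, 0.463 and -0.00108 for anti-PD-L1 with the combination. The observed covariances of 0.243, 0.173 and 0.215, in this order, exceeded the simulated ones of 0.0645, 0.0638 and 0.064 by 0.178, 0.109 and 0.151. Over genes, Spearman's rho of the log2 change with GC content was -0.589 for anti-PD-L1, -0.435 for sonidegib and -0.552 for the combination. A GC trend common to the vehicle libraries can stay when they are split. The r and covariances of these 3 comparisons therefore do not tell shared drug effects from such a trend. No gene was called in more than 1 of these comparisons, since limma called 0 genes in both single treatments.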

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

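The tests of library scaling, of the GC content trend, of both trends on the called genes and on the 20 most changed genes, of a lower tumour cell share, and of an exchange of vehicle replicate 4 and combination replicate 1 were chosen only after the results they address were seen.

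Single libraries stood apart from the other 3 of their group in 13 of 148 checks of values per group, where chance gives about 7.4. Slc2a1 was at 58.5 FPKM in combination replicate 1 against 7.73 to 13 in the other combination libraries, and Nes (14.9 FPKM) and Slco2a1 (12.1 FPKM) were high in the same library. Hspa1a reached 61.8 FPKM in vehicle replicate 4 against 11.2 to 16.4 in the rest of its group. Anti-PD-L1 replicate 4 was high for Cbr2 (69.2 FPKM), Espn (8.16 FPKM), Alkal2 (16.3 FPKM) and Cd4 (1.42 FPKM), and sonidegib replicate 2 for Espn (8.92 FPKM). Cd274 was at 0.555 FPKM in anti-PD-L1 replicate 2, below the other 3 at 0.668 to 0.689. Hhip was at 0.0133 FPKM in anti-PD-L1 replicate 2 and 0.00434 FPKM in sonidegib replicate 1 and listed at 0 in the others of both groups. The estimated depth of combination replicate 2, 43 M fragments, lay below the 48.5 to 49.2 M of its group. The difference in Alkal2 between the effects of the single drugs and of both, -3.68 on the log2 scale, was a difference between groups by the interaction test.

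For the 1703 genes called between the combination and vehicle, unequal library scaling as the cause is argued against by 2772 calls after median-of-ratios scaling, and a GC content trend as the whole cause by the 386 of them that stayed among 572 calls with it removed, although the median log2 size of the called genes went from 1.19 to 0.696 and the GC slope as a covariate left 0 calls. With the GC and length trends removed 28 genes were called, a count that met the bound set for these trends as the cause, and 26 of them were among the 1703. However, the calls ended partly because the median log2 size of the 1703 genes went from 1.19 to 0.66, while their median SE went from 0.329 to 0.223. Because 748 genes then lay under an adjusted p of 0.06 and 2386 under 0.1, against 2266 and 3828 uncorrected, these trends and the treatment cannot be told apart for the called genes, a condition added after those counts were seen. The 20 most changed named genes kept 81.1% of their median size, but 4 of them stayed called and genes picked for their size exclude nothing. An exchange of vehicle replicate 4 and combination replicate 1 also cannot be told apart from correct labels: of 6008 genes called between the other 3 libraries of each group, vehicle replicate 4 lay on its labelled side for 29.6% and combination replicate 1 for 37.1%, although AY036118 and Ccl8, themselves called with these labels, followed the labels in both libraries. These 2 libraries also lay apart from their groups in GC slope (-0.513 and 2.13). The percents were not computed with the GC trend removed, so they do not tell an exchange from that trend.

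The shifts of the T cell, antigen presentation and hypoxia lists between the combination and vehicle were weighed together. GC content and length trends as their cause are argued against by camera with both trends removed, at an adjusted p of 0.00158 or lower for both immune lists and 2.15e-08 for hypoxia. The tested T cell markers passed a filter that favours such a shift, so for that list the test says less. A single library as the cause of the hypoxia shift is argued against by an adjusted p of 5.36e-08 at most when each of the 8 libraries was left out. A lower share of tumour cells that raised all stromal markers alike is argued against by the endothelial list, whose median lay at -0.344 relative to all genes (-0.107 with both trends removed). The gap of the fibroblast score to the endothelial score (0.833, SE 0.24, and 0.737, SE 0.198 with both trends removed) also argues against it. All 24 listed fibroblast genes were tested. The gap of the T cell score was 1.28 (SE 0.458), and 1.03 (SE 0.421) with both trends removed. That score rests on the 7 of 23 T cell markers that passed a filter favouring a difference between groups, so its gap cannot decide. The fibroblast (0.527, SE 0.151), macrophage (0.382, SE 0.171) and adipocyte (1.00, SE 0.542) scores were higher too. A lower share of tumour cells in which endothelial markers moved apart from the other stromal markers is therefore not excluded. These tests leave open the correlation between genes and the exchange of libraries above. Camera with an estimated correlation called no list, while fry called 4 for the combination against vehicle.

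Each count was set against other splits of the same libraries into groups of these sizes, and chance could not be excluded for any comparison of the design. For the combination against vehicle 2 of 35 splits called as many genes as the real 1703, and the other, which exchanged vehicle replicate 4 and combination replicate 1, called 5315. It parts the libraries with a GC slope above 2 from the rest and so points to a structure of the libraries. With the GC trend removed 2 of 35 splits called as many as the real 572 (highest other 2901), and with both trends removed 3 of 35 as many as the real 28 (highest other 3036), the same exchange in both. With 0 genes called, all 35 splits were as large for anti-PD-L1 against vehicle (highest 1931, after exchanging vehicle replicate 4 and anti-PD-L1 replicate 4), sonidegib against vehicle (3122, after exchanging vehicle replicate 4 and sonidegib replicate 2), the combination against sonidegib (273) and sonidegib against anti-PD-L1 (1). The combination against anti-PD-L1 had 9 of 35 splits with at least its 1 gene (highest 37), the difference across groups 8 of 100 drawn splits with at least 3 (highest 2508), and the interaction 14 of 100 with at least 1 (highest 1341).

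Counts of called lists were as large in 33 of 35 splits for anti-PD-L1 against vehicle (real 2, highest other 16), 24 for sonidegib against vehicle (5, 14), 33 for the combination against vehicle (5, 12) and 34 for sonidegib against anti-PD-L1 (1, 17). For the combination against anti-PD-L1 they were as large in 2 (14, 17) and against sonidegib in 4 (13, 16), so chance was not excluded there either.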

How the results depend on the processing

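Median-of-ratios scaling, trend removal, the GC slope covariate, array weights, the split of the vehicle libraries and the omission of 5 libraries were chosen only after the data were seen. No called named gene changed sign in any alternative. With both trends removed 68 of 73 called values of named genes lost their call, with the GC trend alone 48 of 73, with no filter 71 of 74, with quantile normalization 22 of 74, with median-of-ratios scaling 13 of 74, and with the GC slope covariate all 74. The alternatives planned for read counts were not run, since the values are FPKM. Depth limits values near that of 1 fragment, which on a 2 kb transcript is worth 0.0098 to 0.0161 FPKM. Where no construction shows it, the cause was not tested.

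Quantile normalization gave 0 genes across the groups (3 in the reported fit), 2634 for the combination against vehicle (1703), 0 for the combination against anti-PD-L1 (1), 0 for the interaction (1) and 2 lists for sonidegib against vehicle (5). Median-of-ratios scaling gave 0, 2772, 0, 0 and 3. No filter gave 8 genes for the combination against vehicle, 3 for the combination against anti-PD-L1 and 0 for the interaction, and it tested many more genes. A mean of at least 1 FPKM gave 0 for the interaction. A pseudocount of 0.1 gave 0 genes across the groups, 0 for the combination against anti-PD-L1 and 0 for the interaction. Fits on only the 2 groups compared, with fewer libraries for the spread, gave 4 genes for anti-PD-L1 and 4 for sonidegib against vehicle, 27 for the combination against vehicle, 2 for the combination against sonidegib and 2 for sonidegib against anti-PD-L1. Camera with an estimated correlation called 0 lists in all 6 comparisons. Fry called 4 for the combination against vehicle and 0 in the other 5.

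The replicate numbers do not pair the tumours: the mean correlations of same-numbered deviations were -0.118, -0.0681, 0.0076 and -0.0444, and 0 of 16 libraries correlated best with their own number. With the replicate block 0 genes were called across the groups, 0 for the combination against anti-PD-L1 and 0 for the interaction, and no other count moved by over 1.5 times. The replicate block with both trends removed gave 0 genes across the groups, 0 for the combination against vehicle, 0 for the combination against anti-PD-L1 and 0 for the interaction, and 1, 0 and 0 lists for anti-PD-L1 against vehicle, sonidegib against vehicle and sonidegib against anti-PD-L1.

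With the GC trend removed the counts were 0 across the groups, 572 for the combination against vehicle, 0 for the combination against anti-PD-L1 and 0 for the interaction. With both trends removed they were 0, 28, 0 and 0. Either removal left 1 list for anti-PD-L1 against vehicle, 0 for sonidegib against vehicle and 0 for sonidegib against anti-PD-L1. The GC slope covariate gave 0 across the groups, 0 for the combination against vehicle and 0 for the interaction. Array weights gave 4700 across the groups, 2024 for anti-PD-L1, 1 for sonidegib and 5755 for the combination against vehicle, 2290 and 590 for the combination against anti-PD-L1 and sonidegib, 3 for sonidegib against anti-PD-L1, 0 for the interaction, and 1682 genes shared by comparisons against vehicle (0). Without the 5 libraries with a GC slope above 2, which leaves 1 vehicle library assumed to vary like the other groups, these counts were 245 across the groups, 2 for sonidegib and 233 for the combination against vehicle, 943 and 27 for the combination against anti-PD-L1 and sonidegib, 4 for sonidegib against anti-PD-L1 and 2 shared. The lists were then 8 for anti-PD-L1 and 9 for the combination against vehicle and 2 for sonidegib against anti-PD-L1. With the vehicle libraries split, the highest number of shared genes was 2.

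Leaving out each library in turn gave 0 (several libraries) to 3331 genes (without vehicle replicate 4) across the groups, and 0 to 3929, 0 to 3980 and 3 to 4953 for anti-PD-L1, sonidegib and the combination against vehicle, each highest without vehicle replicate 4. The lowest count, 3, came without vehicle replicate 3 and again without combination replicate 4. It gave 0 to 216, 0 to 117 and 0 to 5 for the combination against anti-PD-L1, against sonidegib and the interaction, each highest without combination replicate 1. It gave 0 to 1 for sonidegib against anti-PD-L1 and 0 to 3995 shared genes. Lists ranged from 1 to 4 for anti-PD-L1, 4 to 6 for sonidegib and 5 to 9 for the combination against vehicle, 11 to 15 for the combination against anti-PD-L1 and again against sonidegib, and 0 to 6 for sonidegib against anti-PD-L1.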

Other observations

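The contrast of the 8 libraries with sonidegib against the 8 without, the test of its splits and the test of ribosomal RNA were chosen only after AY036118 was seen. The S numbers of all libraries with sonidegib follow those of all libraries without it. In this contrast library order and sonidegib therefore cannot be told apart. In this contrast Alox5ap, which activates 5-lipoxygenase for leukotriene synthesis, was at 4.03 ± 1.27 and 4.2 ± 0.945 FPKM (SD, n = 4) with vehicle and anti-PD-L1, and at 11.5 ± 4.29 and 11.7 ± 2.97 with sonidegib and the combination (log2 change 1.27, SE 0.20, adjusted p = 0.0393 by limma). Dram1, a p53-regulated autophagy gene, was at 0.624 ± 0.222, 1.1 ± 0.219, 3.02 ± 1.42 and 2.99 ± 1.18 FPKM in the same order (1.06, SE 0.18, adjusted p = 0.0465). Ccl8 (1.78, SE 0.30) and Ly6c1 (1.33, SE 0.22) rose as well, each with an adjusted p = 0.0418. Limma called these 4 genes and AY036118 (9.69, SE 1.02, adjusted p = 0.0063), with 3019 at an unadjusted p under 0.05, while the matching contrast for anti-PD-L1 called 0, with 2377. Of 100 drawn splits 1, the real one, gave 5 genes and the highest other gave 1, but the contrast was chosen on these same libraries, so this does not exclude chance. With 1 library left out the count was lowest at 1 and highest at 1427 (without combination replicate 1), with 1316 without vehicle replicate 4. Quantile normalization, median-of-ratios scaling and the removal of both trends left 1 gene each, and the GC slope covariate left 0. The calls of Alox5ap, Ccl8 and Ly6c1 were lost in 19 of 29 alternatives each and that of Dram1 in 22.

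To test a larger share of ribosomal RNA with sonidegib, the FPKM of 3 genes of that ribosomal RNA locus (CT010467.1, Gm26917 and Gm42418) were summed. The log2 mean of the sum was -0.815 in libraries with sonidegib relative to those without. This sum leaves out AY036118, so reads assigned to AY036118 would lower it. CT010467.1, which contains AY036118, was at 2060 to 9780 FPKM with sonidegib and 2110 to 6310 without. The sum therefore cannot decide whether a larger share of ribosomal RNA was the source of AY036118. A different division of reads between AY036118 and the genes that overlap it is possible as well. That sum was lower where AY036118 was listed high, and FPKM values do not show how reads were divided. Vehicle replicate 3, the exception among libraries without sonidegib, was listed at 215 FPKM.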
